A study of Zea mays with 72 samples.

How the data were processed

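RNA from 72 maize leaf samples was sequenced as BGI DNBSEQ libraries, with 6 biological replicates for each of 12 combinations of leaf and treatment. Bowtie2 and RSEM were used with the assembly B73 RefGen_v4, per the submitters' processing notes, which give no versions. The deposited tables hold expected counts per gene, not scaled between samples by the authors, and FPKM values, which the authors scaled per sample to gene length and mapped fragments. Of the values above 0 in the count table, 11.09% were not whole (tolerance 1e-06), as RSEM divides reads between similar genes. Levels of near-identical gene copies are therefore uncertain. Expected counts were rounded to whole numbers. FPKM values were not used in any comparison here.

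The table had 43547 entries, of which 11312 were blank in every sample, and the other 32235 were genes with values. Their identifiers are NCBI Gene numbers. Names were taken from the reference table of the assembly Zm-B73-REFERENCE-NAM-5.0, which differs from the assembly of the reads, so no coordinates are given. It held 30403 of the genes, with 99.74% of the counts, and a name other than a locus number for 2547. Numbers in brackets after a symbol are NCBI Gene numbers, and pep1 stands for the gene of that symbol listed as a phosphoenolpyruvate carboxylase. Total counts per library ran from 26212027 to 31052273 (median 29911694), and no pair of libraries was identical.

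Genes with low counts were removed with filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 25558 genes, 2320 of them with a name. Counts were scaled by TMM and fitted with a robust quasi-likelihood model with 1 coefficient per group (common dispersion 0.0631). The 27 contrasts were 9 of treatment against the control of the same leaf, 9 of differences in a treatment's effect between leaves, 6 between times or agents within a leaf, and 3 between control leaves. The p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the genes of each contrast, at a threshold of 0.05. Log2 fold changes are given with ± SE, and CPM as mean ± SD over 6 libraries. Each leaf had 1 control group, which served all of its treatments. Log2 CPM for principal components used a prior count of 2.

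Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation. A result with an estimated correlation is given where it ended a call. Of 36 lists fixed before the data were examined, 24 had a member in the table, and 17 lists were added afterwards. In all, 36 lists with at least 3 tested genes were tested as sets. For fixed lists, counts past the threshold are given over all genes and adjusted over the list alone.

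The rule for naming genes was also set before the data were examined. It took, for each treatment and control-leaf comparison, the 8 largest rises and 5 largest falls past the threshold with complete separation of the groups, at least 5 CPM in the higher group and a name. For the other contrasts it took the 5 largest in each direction. It further took up to 4 members of each list with the smallest adjusted p, and a set of known defence and photosynthesis genes. A gene named for one comparison is also given in the parallel comparisons of other leaves and treatments, and which of these genes appear in the text was chosen after their values were seen.

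The fit was tested on simulated counts drawn from the real means and library sizes. For the comparison of leaf 5 after 30 min of HAC with its control, 80% of the 2-fold and 99% of the 4-fold changes among 200 changed genes were recovered at 25343 genes tested, and 9 of 188 calls were false. For the difference of this effect between leaves 5 and 4, 57% and 92% were recovered, and 8 of 157 calls were false. A simulated comparison without changes in leaf 4 gave 0 calls.

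Shared responses to HAC and ZmPep3 within a leaf were taken from edgeR fits of the 3 groups at 2 h of that leaf alone and compared with simulated unchanged groups and with the 6 controls split 3 and 3, since both agents were set against the same controls. Alternatives for every contrast were DESeq2 size factors in edgeR, no filter beyond a total count above 0, a filter of a mean CPM of at least 1 in at least 1 group, a block for the replicate number, the DESeq2 1.42.0 Wald test, and a fit of only the groups of the contrast. Fits without leaf 6 control libraries 5 and 6, without leaf 5 ZmPep3 libraries 1 and 6, and without leaf 4 HAC 30 min libraries 5 and 6, were added after the data were seen. The replicate numbers were checked for pairing across groups: of 396 pairs of libraries with the same number, 23 had a residual correlation over 0.1, and the median was 0.009, so they were not treated as pairs. For each gene named, the log2 fold change was also computed without each library in turn, at the dispersions of the full fit, and values that 1 library moved by more than 1.5 times are given with that library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. No sample was left out. Transcript isoforms were not analysed here.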

Results

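RNA was measured in 72 libraries from detached leaves of maize (Zea mays) seedlings of the inbred line B73, made up of 12 groups of 6 biological replicates. Leaf 4 was mature, and leaves 5 and 6 were immature. Leaves of each age were kept as controls, exposed for 30 min or 2 h to (Z)-3-hexenyl acetate (HAC), a green leaf volatile that damaged leaves release, or supplied for 2 h with ZmPep3, a plant elicitor peptide of maize, at about 1 µM in the solution. Leaf 4 needed an additional sheath removal before treatment. The comparisons asked how strongly leaves of different age responded to an airborne and to a dissolved defence cue. Library totals ran from 26212027 to 31052273 counts with a median of 29911694, and 25558 genes were tested. Leaf number accounted for the first principal component of log2 CPM, which held 53.7% of the variance, and treatment separated along the second, with 10.5%.

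**Figure D1:**
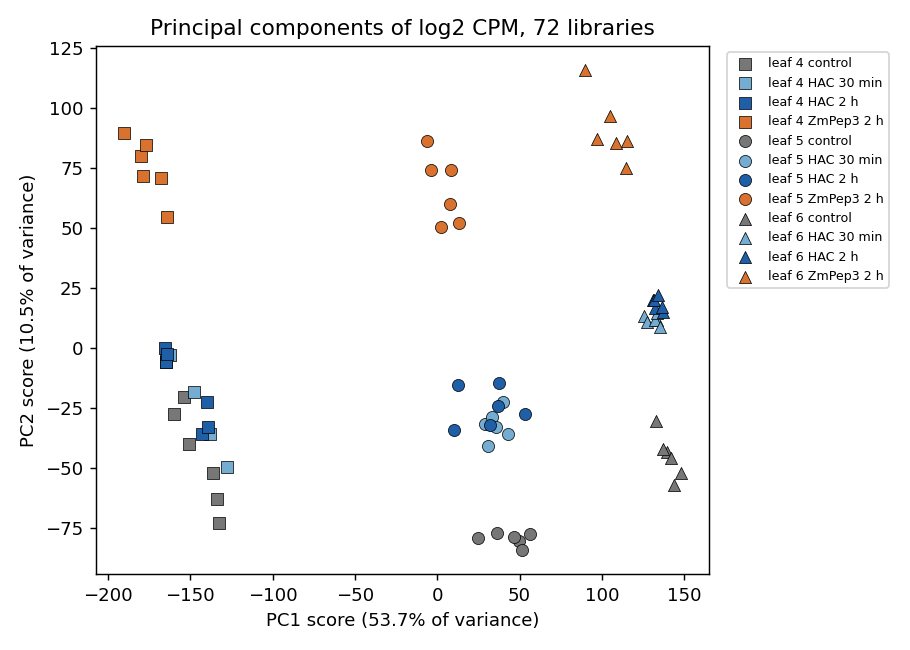
Scores of the 72 libraries on the first 2 principal components of log2 CPM, with symbols for leaves and colours for treatments. Leaves separate along the horizontal axis (53.7% of the variance) and treatments along the vertical axis (10.5%).

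After 30 min of HAC, transcripts of jasmonate repressors and of several basic helix-loop-helix (bHLH) regulators rose in leaves 4, 5 and 6. TIFY20 (NCBI Gene 100286212), a member of the JAZ repressors of jasmonate-responsive transcription, rose 12.9-fold in leaf 4, 132-fold in leaf 5 and 104-fold in leaf 6. Its mean level went from 0.441 ± 0.138 to 58.1 ± 12.3 CPM in leaf 5 and from 1.59 ± 0.499 to 20.5 ± 6.47 CPM in leaf 4 (SD, n = 6). bHLH116 (100284818) rose 11.5-fold in leaf 4, 489-fold in leaf 5 and 307-fold in leaf 6. The leaf 6 value, a log2 change of 8.26, was 9.30 without leaf 6 control library 4. dxs2 (606430), encoding the enzyme that starts the plastid isoprenoid pathway, rose 4.10-fold, 21.5-fold and 41.4-fold in the 3 leaves.

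Genes of the jasmonate pathway responded early to HAC. Of the 7 measured jasmonate repressor and catabolism genes, 5 rose in each leaf over all genes tested and none fell (5, 5 and 6 rose when adjusted over the list alone). The list stood above other genes by camera with adjusted p of 1.1e-18, 8.16e-19 and 1.93e-17 in leaves 4, 5 and 6. In the wider TIFY family of 21 genes, a list set after the data were seen, 15, 16 and 16 members rose, among them TIFY28 with log2 fold changes of 3.46 ± 0.29 (SE), 6.06 ± 0.33 and 5.19 ± 0.32, and TIFY9 with 2.54 ± 0.27, 5.95 ± 0.32 and 5.56 ± 0.32. bHLH108 rose by 2.09 ± 0.29, 5.85 ± 0.35 and 4.09 ± 0.31, and bHLH76 by 2.37 ± 0.27, 4.93 ± 0.31 and 4.73 ± 0.30. Jasmonate synthesis and conjugation genes rose in 2, 7 and 9 of 13 cases (3, 8 and 9 adjusted over the list alone). ts1 (100037808), a 13-lipoxygenase known from tasselseed mutants, rose by 0.88 ± 0.18, 2.70 ± 0.19 and 2.77 ± 0.19, and aos1, an allene oxide synthase, by 0.88 ± 0.26, 1.36 ± 0.26 and 1.28 ± 0.26. The camera call of this list was reached in leaves 5 and 6 (adjusted p = 0.000147 and 2.65e-07) and not in leaf 4 (0.129). With an estimated correlation the adjusted p was 0.0793 in leaf 5 and 0.0181 in leaf 6.

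Part of the volatile list responded early as well. In the terpene and indole volatile list of 15 genes, 3, 7 and 6 rose in leaves 4, 5 and 6 (3, 8 and 8 adjusted over the list alone), with camera adjusted p of 8.1e-04, 2.08e-05 and 3.38e-08. The leaf 4 call had adjusted p = 0.0818 with an estimated correlation. CYP92C5 (103631958), a cytochrome P450 that makes the homoterpene DMNT, rose by 1.77 ± 0.24, 3.52 ± 0.26 and 4.48 ± 0.28. AAMT1 (100500707), a methyltransferase that makes methyl anthranilate, rose by 0.93 ± 0.28, 2.26 ± 0.28 and 2.95 ± 0.29. Igl (100273163), the lyase that releases free indole, rose by 1.28 ± 0.25 in leaf 5 and 3.17 ± 0.27 in leaf 6, against 0.61 ± 0.25 in leaf 4, which did not pass. Of the 4 isoprenoid precursor genes, 1, 2 and 1 rose (2, 4 and 1 adjusted over the list alone), with camera adjusted p of 0.000238, 8.34e-05 and 0.0053.

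Genes outside these pathways also moved within 30 min. Among 5 ethylene synthesis and receptor genes, 1, 2 and 2 rose in leaves 4, 5 and 6, also when adjusted over the list alone. acs7, an ACC synthase that forms the precursor of ethylene, rose by 1.01 ± 0.26, 2.11 ± 0.26 and 2.19 ± 0.26. WRKY97 (100280987) rose 36.9-fold in leaf 5 and 39.3-fold in leaf 6, and changed by 0.87 ± 0.33 in leaf 4 without passing. The CONSTANS-like genes COL5 and COL10 fell in each leaf, COL5 by log2 values of -1.27 ± 0.27, -1.76 ± 0.26 and -0.96 ± 0.24 and COL10 by -0.84 ± 0.15, -1.44 ± 0.15 and -0.99 ± 0.15. Of 4 circadian clock genes, 0, 2 and 2 fell (0, 2 and 4 adjusted over the list alone), and PRR59 changed by -0.47 ± 0.09 in leaf 5. The clock list had camera adjusted p of 0.00576 in leaf 5, and adjusted p = 0.0793 with an estimated correlation. The labels do not give the hour at which control leaves were harvested.

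In total, 1119 genes passed in leaf 4 after 30 min (646 higher and 473 lower), 3298 in leaf 5 (2083 and 1215) and 2990 in leaf 6 (2169 and 821). Changes of at least 2-fold made up 342, 1213 and 1295 of them. In leaf 4, libraries 5 and 6 stood apart from the other 4 at this time, and 1549 genes passed without them (850 higher and 699 lower).

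**Figure D2:**
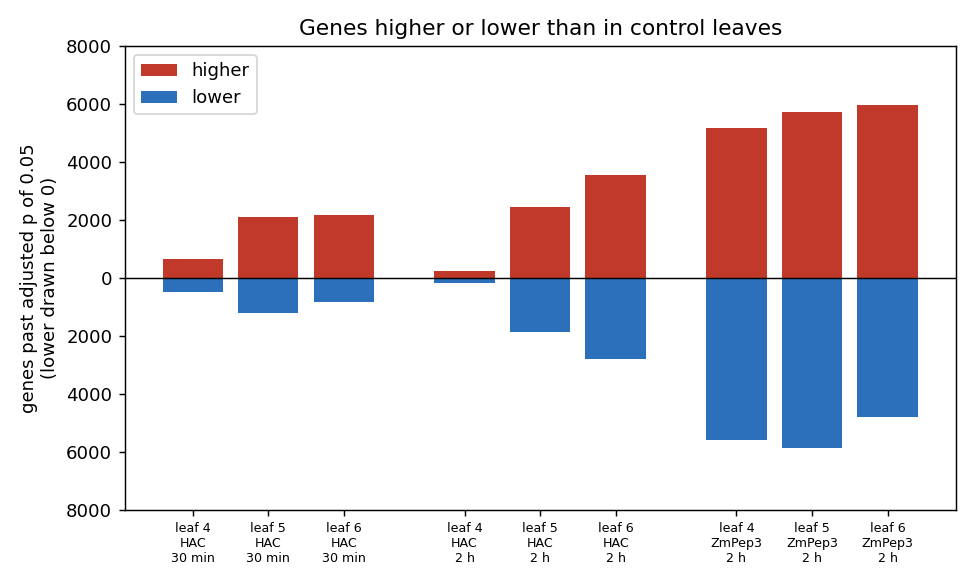
Number of genes higher (above 0) and lower (below 0) than in the control of the same leaf at an adjusted p of 0.05, for each leaf and treatment. HAC called 1119 and 431 genes in leaf 4 and between 2990 and 6354 in leaves 5 and 6, while ZmPep3 called between 10762 and 11605 in each leaf.

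After 2 h of HAC, most members of the terpene and indole volatile and lipoxygenase lists were higher in leaves 5 and 6. tps10 (732751), the sesquiterpene synthase that makes the farnesene and bergamotene emitted after herbivory, rose 262-fold in leaf 5 and 273-fold in leaf 6, from 0.462 ± 0.258 to 122.5 ± 59.2 CPM and from 0.947 ± 1.04 to 252 ± 30.1 CPM (SD, n = 6). The leaf 6 log2 change of 8.09 was 8.75 without leaf 6 control library 5. In leaf 4 it stood at 109 ± 88.0 CPM in controls and 196 ± 99.6 CPM after 2 h, a log2 difference of 0.85 ± 0.48 with an edgeR adjusted p of 0.415. lox5 (100037804), a 9-lipoxygenase, rose 2.98-fold in leaf 4, 37.2-fold in leaf 5 and 17.9-fold in leaf 6.

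The terpene and indole volatile list had 2, 12 and 13 of 15 members higher in leaves 4, 5 and 6 (5, 12 and 13 adjusted over the list alone) and 1 lower in leaf 5, with camera adjusted p of 0.000239, 2.8e-14 and 4.12e-17. TPS2 (732758) and TPS3 (732759), which carry terpene synthase symbols, rose by log2 values of 3.30 ± 0.29 and 3.09 ± 0.33 in leaf 5 and of 5.78 ± 0.33 and 5.24 ± 0.38 in leaf 6, against 0.90 ± 0.27 and 0.64 ± 0.30 in leaf 4, where neither passed. After 2 h, TPS2 stood at 447 to 804, 269 to 564 and 235 to 349 CPM in leaves 4, 5 and 6. TPS3 stood at 169 to 383, 60.0 to 160 and 29.45 to 54.8 CPM. Leaf 4 controls already held 186 to 500 CPM of TPS2 and 105 to 249 CPM of TPS3. Leaf 6 controls held 2.60 to 10.65 and 0.562 to 2.06 CPM. CYP92C5 rose by 1.42 ± 0.24, 3.33 ± 0.26 and 6.23 ± 0.30, and AAMT1 by 1.48 ± 0.28, 4.84 ± 0.31 and 5.84 ± 0.33. The indole genes Igl and igl1 changed by 0.45 ± 0.25 and 0.03 ± 0.17 in leaf 5, neither past the threshold, and by 2.56 ± 0.27 and 0.54 ± 0.18 in leaf 6.

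Most listed lipoxygenases rose in leaves 5 and 6 as well. The 7 genes of the list of 9-lipoxygenases and other lipoxygenases had 1, 6 and 6 higher (6, 6 and 6 adjusted over the list alone; camera adjusted p = 6.62e-05, 2.8e-14 and 4.71e-11). lox1, lox2 and lox3 rose by 2.77 ± 0.27, 2.96 ± 0.28 and 2.93 ± 0.31 in leaf 5. In jasmonate synthesis, 2, 9 and 9 of 13 rose (5, 10 and 10 adjusted over the list alone) and 0, 1 and 1 fell, with camera adjusted p of 0.00298, 3.01e-13 and 4.63e-11. The leaf 4 call had adjusted p = 0.285 with an estimated correlation. opr7, a 12-oxophytodienoate reductase, rose by 0.64 ± 0.15, 1.76 ± 0.15 and 2.75 ± 0.16, and aos2, annotated as an allene oxide synthase, by 3.47 ± 0.26 in leaf 5 and 2.99 ± 0.25 in leaf 6. lox10, a 13-lipoxygenase that feeds green leaf volatile synthesis, rose by 1.37 ± 0.18 and 1.70 ± 0.18 in leaves 5 and 6.

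Of the 7 jasmonate repressor and catabolism genes in leaf 4, 0 passed the threshold over all genes at 2 h. Adjusted over the list alone, 3 were higher and 1 lower. TIFY20 changed there by 0.69 ± 0.26 and JAZ9 by 0.92 ± 0.36. In leaves 5 and 6, 6 and 7 of them rose, in the same numbers adjusted over the list alone (camera adjusted p = 1.05e-11 and 3.29e-11). The leaf 4 list had a camera adjusted p of 0.0382, with adjusted p = 0.52 with an estimated correlation.

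Parts of the lists for defence metabolism and defence proteins rose at 2 h in leaves 5 and 6. Of 13 benzoxazinoid synthesis genes, which make the hydroxamic acids of grasses, 0, 9 and 10 rose (6, 10 and 10 adjusted over the list alone), with camera adjusted p of 0.00116, 4.03e-10 and 2.28e-14. In leaf 4 the adjusted p was 0.377 with an estimated correlation. bx6 (541977) rose by 1.67 ± 0.19 in leaf 5 and 3.45 ± 0.21 in leaf 6, and Bx7 (100147731), a methyltransferase late in the pathway, by 1.64 ± 0.18 and 3.03 ± 0.19. Of 16 antifeedant and antimicrobial protein genes, 2, 5 and 7 rose, with the same numbers adjusted over the list alone, where 1 also fell in leaf 5. The camera adjusted p values were 0.00298, 0.011 and 0.00367, and none of the 3 calls held: adjusted p = 0.268, 0.205 and 0.172 with an estimated correlation. MPI (542408), a maize proteinase inhibitor, rose by 2.51 ± 0.35 in leaf 5 and 1.03 ± 0.33 in leaf 6.

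Single genes that fell after 2 h in leaves 5 and 6 included the response regulators RR6 and RR7, which cytokinin induces. RR6 changed by -0.58 ± 0.19 and -1.92 ± 0.20, and RR7 by -1.22 ± 0.34 and -2.35 ± 0.33. an1, an enzyme of gibberellin synthesis, changed by -1.51 ± 0.39 in leaf 5 and -1.59 ± 0.35 in leaf 6. see2b, a vacuolar cysteine protease raised in senescing leaves, changed by -1.04 ± 0.19 and -1.62 ± 0.19. Of 4 ligule and sheath genes, markers of another part of the leaf, 2 fell in leaf 4, also when adjusted over the list alone (camera adjusted p = 0.00635), lg2 among them with -0.73 ± 0.20.

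At 2 h, 431 genes passed in leaf 4 (236 higher and 195 lower), 4308 in leaf 5 (2452 and 1856) and 6354 in leaf 6 (3550 and 2804). The leaf 4 count was sensitive to the model, at 659 genes with DESeq2 and 87 when only the leaf 4 control and 2 h libraries were fitted.

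**Figure D3:**
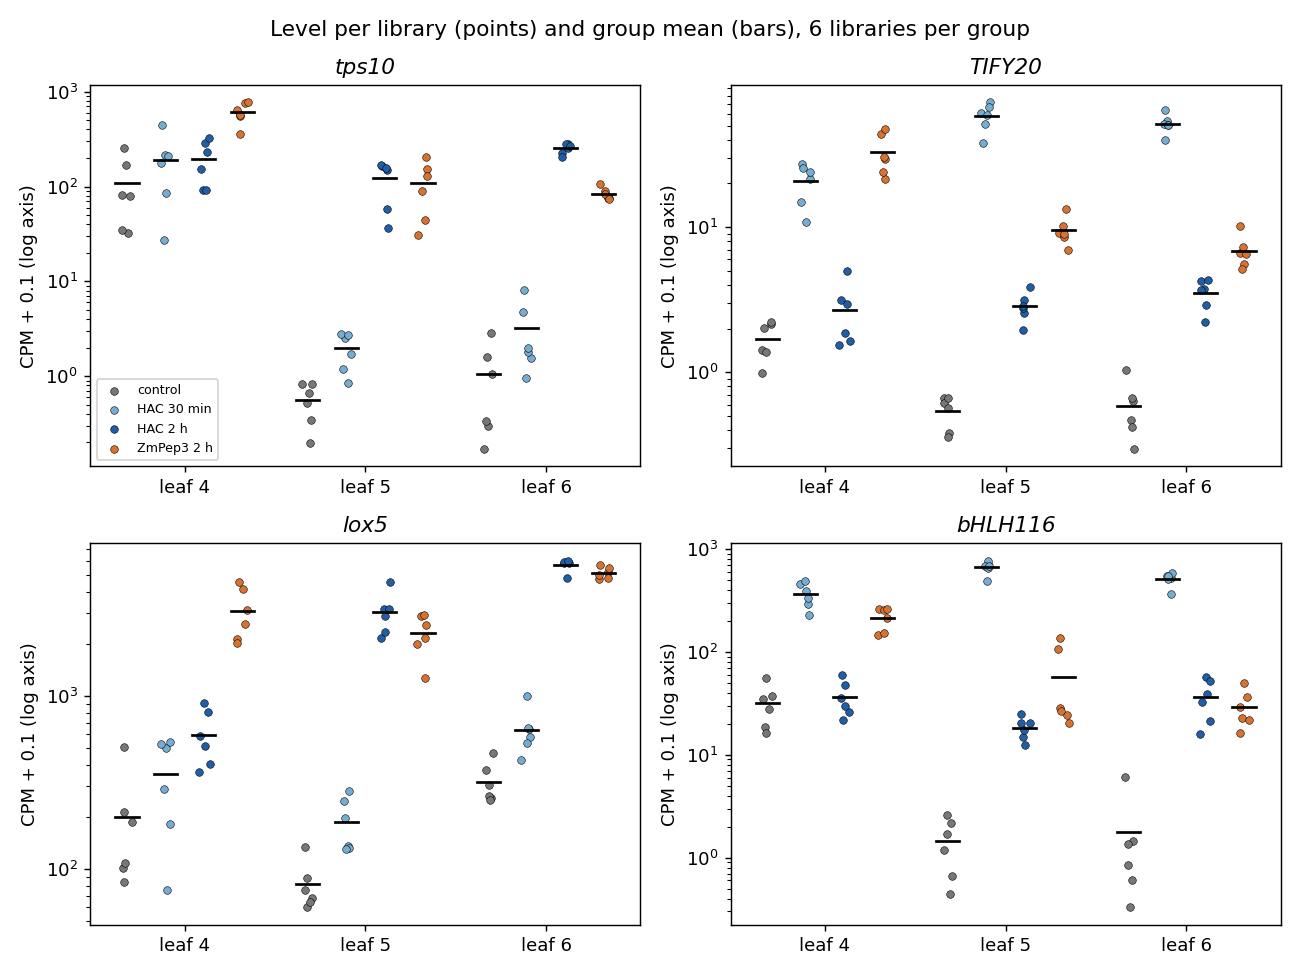
Level of tps10, TIFY20, lox5 and bHLH116 in each library (points, CPM plus 0.1 on a log axis) with the group mean (bars), by leaf and treatment, 6 libraries per group. tps10 controls lie near 109 CPM in leaf 4 and below 1 CPM on average in leaves 5 and 6.

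Whether the response to HAC differed between leaves was tested directly, as the difference between fold changes. Contrasts with leaf 4 hold its additional sheath removal as well as leaf age. A larger fold change can start from a lower control level. bHLH116 controls held 16.1 to 55.3 CPM in leaf 4 and 0.344 to 2.495 CPM in leaf 5. After 30 min of HAC it stood at 226 to 486 and 493 to 773 CPM. After 2 h, tps10 stood at 91.1 to 324, 36.2 to 169 and 207 to 282 CPM in leaves 4, 5 and 6. TIFY20 and WRKY97 stood higher in leaves 5 and 6 than in leaf 4 after 30 min. At 30 min, bHLH116 rose by 5.41 ± 0.62 log2 units more in leaf 5 than in leaf 4 and by 4.73 ± 0.61 more in leaf 6 than in leaf 4 (5.78 without leaf 6 control library 4). WRKY97 rose by 4.34 ± 0.50 and 4.43 ± 0.49 more, and TIFY20 by 3.35 ± 0.38 and 3.02 ± 0.38 more. At 2 h, tps10 rose by 7.18 ± 0.83 more in leaf 5 and 7.24 ± 0.80 more in leaf 6 than in leaf 4, with edgeR adjusted p of 1.16e-08 and 2.34e-10, and the leaf 6 value was 7.90 without leaf 6 control library 5.

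Parts of several gene lists had larger log2 fold changes in leaves 5 and 6 than in leaf 4. Jasmonate repressor and catabolism genes responded more in leaf 5 than in leaf 4 at 30 min. Of 7, 4 were past the threshold (5 adjusted over the list alone, camera adjusted p = 3e-09). In leaf 6 there were also 4 (5 adjusted over the list alone, camera adjusted p = 1.3e-06). At 2 h, 5 of 15 terpene and indole volatile genes responded more in leaf 5 than in leaf 4 (9 adjusted over the list alone; 1.03e-10) and 8 in leaf 6 (9 adjusted over the list alone; 5.12e-14). For jasmonate synthesis the 2 h numbers were 7 in each young leaf, with 1 lower in leaf 6 (9 and 7 adjusted over the list alone; 3.03e-11 and 8.74e-09), and for the lipoxygenases 5 and 6 of 7 (6 and 6 adjusted over the list alone; 2.73e-11 and 1.73e-07). dxs2 rose by 2.43 ± 0.38 and 4.81 ± 0.40 more, and CYP92C5 by 1.91 ± 0.34 and 4.81 ± 0.36 more, in leaves 5 and 6 than in leaf 4. GST25, a glutathione transferase, rose by 2.63 ± 0.48 and 3.89 ± 0.50 more. After 2 h, dxs2 stood at 92.1 to 204, 104 to 243 and 136 to 244 CPM in leaves 4, 5 and 6. CYP92C5 stood at 150 to 247, 162 to 413 and 140 to 279 CPM. Levels of dxs2 and CYP92C5 thus overlapped between leaves, and the larger fold changes went with lower controls. dxs2 controls held 40.85 to 101.5, 9.23 to 21.4 and 1.62 to 4.25 CPM. CYP92C5 controls held 46.5 to 108, 12.9 to 31.2 and 0.671 to 3.96 CPM.

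Leaves 5 and 6 also differed from each other in part. At 2 h, 5 of 13 benzoxazinoid genes rose more in leaf 6 than in leaf 5 (8 adjusted over the list alone; camera adjusted p = 5.81e-07, and adjusted p = 0.167 with an estimated correlation). bx6 rose by 1.78 ± 0.27 more in leaf 6 than in leaf 5, Bx7 by 1.39 ± 0.25 and CYP92C5 by 2.91 ± 0.35. Leaf 6 controls started lower, with Bx7 at 211 to 374 CPM against 833 to 1415 in leaf 5. CYP92C5 controls held 0.671 to 3.96 against 12.9 to 31.2 CPM. After 2 h Bx7 stood at 2047 to 3145 CPM in leaf 6 and 2863 to 4180 in leaf 5, and CYP92C5 at 140 to 279 and 162 to 413. Igl rose by 1.89 ± 0.36 more at 30 min and 2.11 ± 0.36 more at 2 h. In the other direction, bHLH20 differed by -2.15 ± 0.48 and -2.53 ± 0.53 (-3.43 without leaf 6 HAC 2 h library 3), and RR6 by -1.35 ± 0.27 at 2 h.

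The response to HAC at 30 min differed for 808 genes between leaves 5 and 4 (686 with the larger log2 fold change in leaf 5, 122 with the smaller), for 1341 between leaves 6 and 4 (1081 and 260) and for 92 between leaves 6 and 5 (67 and 25). At 2 h the numbers were 686 (564 and 122), 2896 (1859 and 1037) and 445 (281 and 164). The contrasts between leaves 6 and 5 grew at both times under the DESeq2 Wald test. They shrank when leaf 6 control libraries 5 and 6 were left out, to 51 genes at 30 min and 275 at 2 h. When only their own 4 groups were fitted the counts were 18 and 245. Genes with the larger, meaning more positive, log2 fold change in leaf 6 made up 72.8% of the 92. The share was 62.7% without those libraries and 61.1% in the fit of 4 groups.

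**Figure D4:**
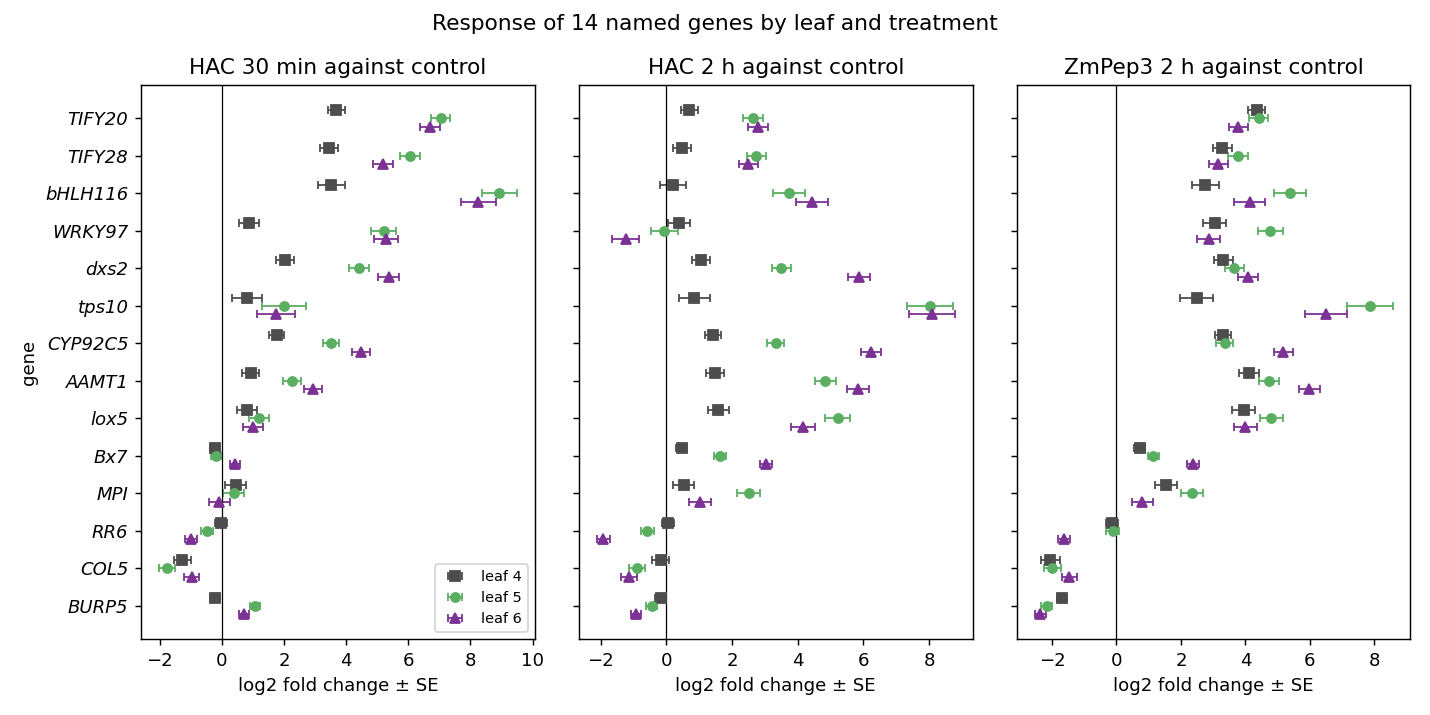
Log2 fold change against the control of the same leaf (points, with SE as bars) of 14 named genes, in leaf 4 (squares), leaf 5 (circles) and leaf 6 (triangles), for HAC at 30 min, HAC at 2 h and ZmPep3 at 2 h. TIFY20 lies at 3.69, 7.04 and 6.70 after 30 min of HAC, and at 4.35, 4.41 and 3.78 after ZmPep3.

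ZmPep3 changed transcripts of the volatile, jasmonate and antimicrobial lists in all 3 leaves, leaf 4 included. tps10 rose 5.61-fold in leaf 4, to 611 ± 154 CPM (SD, n = 6), 233-fold in leaf 5 and 91.0-fold in leaf 6 (a log2 change of 6.51, and 7.17 without leaf 6 control library 5). lox5 rose 15.5-fold, 28.0-fold and 16.1-fold, and reached 3097 ± 1060, 2296 ± 632 and 5139 ± 390 CPM. TIFY20 rose 20.4-fold, 21.2-fold and 13.8-fold. PR-5 (542720), a thaumatin-like antimicrobial protein, rose by log2 values of 2.14 ± 0.40, 3.74 ± 0.43 and 4.72 ± 0.45 (5.33 without leaf 6 control library 5). In leaf 5, ZmPep3 libraries 1 and 6 stood apart from the other 4 in several genes, tps10 among them with 43.9 and 30.8 CPM against 89.5 to 207. Without these 2 libraries tps10 changed there by 8.28 ± 0.70 on the log2 scale, against 7.87 ± 0.70 with them.

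In the terpene and indole volatile list, 11, 12 and 12 of 15 genes rose in leaves 4, 5 and 6 and 1 fell in leaf 5, with the same numbers adjusted over the list alone (camera adjusted p = 8.04e-05, 5.63e-06 and 2.72e-08). AAMT1 rose by 4.10 ± 0.31, 4.73 ± 0.31 and 5.98 ± 0.33, TPS2 (732758) by 2.06 ± 0.27, 3.17 ± 0.29 and 3.92 ± 0.30, and dxs2 by 3.32 ± 0.29, 3.66 ± 0.30 (2.99 ± 0.27 without leaf 5 ZmPep3 libraries 1 and 6) and 4.07 ± 0.31. Of the jasmonate synthesis genes, 10, 9 and 11 of 13 rose and 1 fell in each leaf (10, 9 and 12 rose adjusted over the list alone). Their camera adjusted p values were 1.23e-05, 8.25e-07 and 2.72e-08, and the leaf 4 call had adjusted p = 0.0533 with an estimated correlation. aos1 rose by 3.53 ± 0.29, 2.97 ± 0.28 and 3.18 ± 0.28, and opr7 by 1.47 ± 0.15, 1.67 ± 0.15 and 2.71 ± 0.16. Jasmonate repressor and catabolism genes rose in 6 of 7 cases in each leaf, and 1 fell in leaves 4 and 5. The numbers were the same adjusted over the list alone (camera adjusted p = 6.12e-07, 5.63e-06 and 3.95e-06).

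Antifeedant and antimicrobial genes rose in 9, 9 and 11 of 16 cases (10, 9 and 11 adjusted over the list alone), and 0, 1 and 2 fell (1, 1 and 2 adjusted over the list alone). The calls of this list (camera adjusted p = 0.00353, 0.00214 and 0.028) were lost, at adjusted p = 0.153, 0.113 and 0.294 with an estimated correlation. Beside PR-5, the gene listed as chitinase (542525) rose by 1.84 ± 0.29, 3.97 ± 0.32 and 3.07 ± 0.30, and RIP (541814) by 2.36 ± 0.21 and 2.83 ± 0.22 in leaves 4 and 5. Benzoxazinoid genes rose in 6, 6 and 10 of 13 cases, also when adjusted over the list alone, and Bx7 by 0.72 ± 0.17, 1.14 ± 0.17 and 2.37 ± 0.18. The camera adjusted p of this list was 0.0439, 0.0512 and 7.47e-05, and in leaves 4 and 6 adjusted p = 0.471 and 0.174 with an estimated correlation. Of the 5 ethylene genes, 3, 4 and 2 rose, in the same numbers adjusted over the list alone, acs7 by 3.39 ± 0.27, 2.63 ± 0.26 and 3.22 ± 0.27. Among WRKY factors, a list of 22 set after the data were seen, 10, 14 and 14 rose and 4, 4 and 2 fell (camera adjusted p = 0.0417, 0.000165 and 3.49e-05). The leaf 4 call had adjusted p = 0.217 with an estimated correlation.

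Among single genes with steep changes under ZmPep3, PDC (542376) rose by 5.21 ± 0.63, 5.84 ± 0.68 and 7.82 ± 0.86, and aox3 (542676), a mitochondrial alternative oxidase, by 3.84 ± 0.48, 6.72 ± 0.67 and 7.54 ± 0.73. Levels in controls of the young leaves were near 0: PDC changed by 7.40 in leaf 5 without control library 3 and by 8.78 in leaf 6 without control library 5, and aox3 by 9.43 in leaf 6 without control library 5. The cytokinin oxidase gene CKX4 rose by 3.90 ± 0.28 in leaf 4, 4.51 ± 0.29 in leaf 5 and 4.32 ± 0.29 in leaf 6. PepR1 (100381406), the receptor gene for such peptides, rose by 2.43 ± 0.42, 1.21 ± 0.44 and 1.09 ± 0.42. The aquaporin gene TIP4-4 changed by -4.89 ± 0.51, -1.88 ± 0.39 and -2.32 ± 0.47, and EREB55 by -2.60 ± 0.36, -2.49 ± 0.31 and -1.49 ± 0.30. BURP5 changed by -1.69 ± 0.17, -2.16 ± 0.17 and -2.37 ± 0.17.

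ZmPep3 changed 10788 genes in leaf 4 (5180 higher and 5608 lower), 11605 in leaf 5 (5729 and 5876) and 10762 in leaf 6 (5946 and 4816).

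Tested directly, the response to ZmPep3 differed between leaves 6 and 4 for parts of the volatile and benzoxazinoid lists. Of 7 jasmonate repressor and catabolism genes, 0 differed between leaves 5 and 4 and 1 between leaves 6 and 4. The numbers were the same adjusted over the list alone. TIFY20 differed by 0.05 ± 0.34 between leaves 5 and 4 and by -0.57 ± 0.40 between leaves 6 and 4, neither past the threshold. tps10 responded by 5.38 ± 0.81 more in leaf 5 and 4.02 ± 0.77 more in leaf 6 than in leaf 4 (4.68 without leaf 6 control library 5). Its level under ZmPep3 was highest in leaf 4, at 361 to 774 CPM against 30.8 to 207 in leaf 5 and 73.8 to 107 in leaf 6. tps10 controls held 32.1 to 258, 0.0992 to 0.730 and 0.0702 to 2.755 CPM in leaves 4, 5 and 6. In the terpene and indole volatile list, 6 of 15 responded more in leaf 6 than in leaf 4 (8 more and 1 less adjusted over the list alone; camera adjusted p = 0.0188, and adjusted p = 0.413 with an estimated correlation). Of the 13 benzoxazinoid genes, 6 responded more in leaf 6 than in leaf 4 (7 adjusted over the list alone; camera adjusted p = 0.0188, and adjusted p = 0.634 with an estimated correlation). aoc2, an allene oxide cyclase gene, responded by 1.76 ± 0.19 more in leaf 6 than in leaf 4, bx6 by 2.03 ± 0.27, Bx7 by 1.65 ± 0.25 and PR-5 by 2.58 ± 0.55 (3.19 without leaf 6 control library 5). Bx7 still stood higher in leaf 4 under ZmPep3, at 2682 to 3890 CPM against 1493 to 1858 in leaf 6. Its controls held 1839 to 2820 and 211 to 374 CPM. EREB71 differed by -2.16 ± 0.59 in leaf 5 and -3.77 ± 0.60 in leaf 6 against leaf 4, and vp14, an enzyme of abscisic acid synthesis, by -3.55 ± 0.68 in leaf 6 against leaf 5. Without leaf 6 control library 4 these leaf 6 values were -3.16 for EREB71 and -2.71 for vp14. These differences passed for 1911 genes between leaves 5 and 4 (1361 with the larger log2 fold change in leaf 5, 550 with the smaller), 4759 between leaves 6 and 4 (3123 and 1636) and 529 between leaves 6 and 5 (314 and 215). The last split turned with the scaling, to 208 and 342 under DESeq2 size factors and 289 and 482 in DESeq2, and the count was 335 when only its 4 groups were fitted.

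The 2 times of HAC were also set against each other. Each leaf had 1 control group and none matched to each time, so these values hold any change with time itself as well as the course under HAC. From 30 min to 2 h TIFY20 changed by -2.99 ± 0.24, -4.40 ± 0.26 and -3.91 ± 0.25 in leaves 4, 5 and 6, and bHLH116 by -3.32 ± 0.43, -5.19 ± 0.47 and -3.82 ± 0.44. WRKY97 changed by -5.27 ± 0.40 in leaf 5 and -6.54 ± 0.42 in leaf 6. In contrast, tps10 rose 65.6-fold in leaf 5 and 81.7-fold in leaf 6 between the 2 times, lox5 16.3-fold and 8.96-fold, and GST25 by 3.15 ± 0.36 in both leaves. In leaf 4, tps10 differed by 0.03 ± 0.48 and lox5 by 0.76 ± 0.32 between the times, neither past the threshold. The benzoxazinoid list had 1, 10 and 8 of 13 members higher at 2 h than at 30 min (1, 10 and 9 adjusted over the list alone; camera adjusted p = 0.0241, 2.03e-07 and 3.96e-11). In leaves 4 and 5 this was adjusted p = 0.455 and 0.0771 with an estimated correlation. Jasmonate repressor and catabolism genes had 0, 1 and 3 of 7 higher and 4, 3 and 3 lower. Adjusted over the list alone, 0, 1 and 3 were higher and 5, 4 and 4 lower. The times differed for 919 genes in leaf 4 (380 higher and 539 lower at 2 h), 3931 in leaf 5 (1797 and 2134) and 5263 in leaf 6 (2587 and 2676).

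At the common time of 2 h, ZmPep3 and HAC differed in which genes they raised most. WRKY97 was higher under ZmPep3 by 2.67 ± 0.34, 4.84 ± 0.39 and 4.10 ± 0.40 in leaves 4, 5 and 6, PDC (542376) by 3.61 ± 0.57, 4.75 ± 0.63 and 5.59 ± 0.71, and PR-5 by 1.85 ± 0.39, 2.99 ± 0.41 and 2.67 ± 0.41. Of the 22 WRKY factors, a list set after the data were seen, 8, 12 and 13 were higher under ZmPep3 and 3, 3 and 0 lower (camera adjusted p = 0.0247, 1.04e-05 and 7.9e-08, and in leaf 4 adjusted p = 0.193 with an estimated correlation). Benzoxazinoid genes were lower under ZmPep3 than under HAC in leaf 6, with 9 of 13 lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 0.000712, and adjusted p = 0.339 with an estimated correlation). BX5 differed there by -1.52 ± 0.24 and bx6 by -0.70 ± 0.19. In leaf 6 TPS2 (732758) and TPS3 (732759) were lower under ZmPep3 by log2 values of -1.86 ± 0.27 and -1.81 ± 0.31, and tps10 by -1.58 ± 0.49. In leaf 4 the order was the opposite, with tps10 higher by 1.64 ± 0.49 and TPS2 (732758) by 1.16 ± 0.27 under ZmPep3. The agents differ in dose and route as well as in kind, so these values set the treatments as given side by side. They differed for 7979 genes in leaf 4 (3882 higher and 4097 lower under ZmPep3), 6691 in leaf 5 (3735 and 2956) and 4926 in leaf 6 (3279 and 1647).

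The 2 agents moved many genes in the same direction. This comparison used separate fits of the control, HAC and ZmPep3 libraries of each leaf at 2 h, in which HAC called 53, 3843 and 6386 genes in leaves 4, 5 and 6. Of these, 1967 genes were higher and 1185 lower under both HAC and ZmPep3 in leaf 5, against 520.8 and 295.5 for independent lists, and 65 moved in opposite directions. In leaf 6 the numbers were 2751 and 2285, against 763.2 and 602.5, with 94 opposite, and in leaf 4 they were 34 and 16, against 7.49 and 3.46. With the controls split 3 and 3, so that the agents shared no control library, the medians over 10 splits were 1275 and 555 in leaf 5 and 1949 and 1253 in leaf 6. In leaf 4 they were 0 and 0, as HAC then called a median of 0 genes in edgeR (2705 at an unadjusted p under 0.05), and the number higher under both ran from 0 to 442. Across genes, which are not independent replicates, the log2 fold changes correlated with r of 0.557, 0.637 and 0.675 in leaves 4, 5 and 6. Unchanged groups simulated against the same controls gave 0.493, 0.498 and 0.500 and no shared call. With the split controls, r was 0.299, 0.456 and 0.469. The covariance was 0.339, 0.543 and 0.628, against 0.082, 0.079 and 0.080 in the simulation. Between leaves, which have separate controls, the responses to HAC at 30 min correlated with r of 0.567 for leaves 5 and 6, 0.326 for leaves 4 and 5 and 0.299 for leaves 4 and 6. At 2 h the values were 0.533, 0.248 and 0.187, and for ZmPep3 0.784, 0.680 and 0.584. Each of these was higher over genes with a mean of at least 5 CPM, as at 30 min with 0.837, 0.567 and 0.499.

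Control leaves differed between leaf numbers before any treatment. gar2 (541620) had a mean of 0.339 ± 0.192 CPM in leaf 4, 212 ± 52.9 in leaf 5 and 743 ± 207 in leaf 6, and LPE1 (542332), a leaf permease gene, 0.155 ± 0.196, 36.9 ± 14.8 and 268 ± 37.9 CPM (SD, n = 6). Some volatile genes were lower in the young leaves. tps10 was lower than in leaf 4 by log2 values of -7.86 ± 0.70 in leaf 5 and -6.88 ± 0.66 in leaf 6 (-7.54 without leaf 6 control library 5), TPS3 (732759) by -3.97 ± 0.34 and -7.16 ± 0.41, and CYP92C5 by -1.63 ± 0.24 and -4.83 ± 0.29. The heat shock gene hsp22 was lower by -4.75 ± 0.43 and -5.88 ± 0.47.

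The terpene and indole volatile list had 5 of 15 genes higher and 7 lower in leaf 5 than in leaf 4, and 3 higher and 9 lower in leaf 6, with the same numbers adjusted over the list alone. The leaf 6 call (camera adjusted p = 0.0205) had adjusted p = 0.461 with an estimated correlation. Benzoxazinoid genes were lower in 10 of 13 cases and higher in 3 in each young leaf, also when adjusted over the list alone, and bx6 differed by -1.75 ± 0.19 and -4.56 ± 0.22. The leaf 6 call (camera adjusted p = 0.0195) had adjusted p = 0.841 with an estimated correlation. C4 and Calvin cycle genes were higher than in leaf 4 in 5 and 4 of 6 cases, as were the bundle sheath and mesophyll markers, also when adjusted over the lists alone. pep1, here the gene of that symbol listed as a phosphoenolpyruvate carboxylase, was higher by 1.86 ± 0.20 and 2.08 ± 0.21, and rbcS (542212), a Rubisco small subunit gene, by 1.87 ± 0.18 and 2.13 ± 0.18. In leaf 5 these lists had camera adjusted p of 0.0313 and 0.0104, and adjusted p = 0.56 and 0.531 with an estimated correlation. Markers of tissues that differ between leaf stages also moved: of 7 KNOX and shoot meristem genes 2 and 5 were higher and 1 and 2 lower, and of 4 ligule and sheath genes 2 were higher in each young leaf, in the same numbers adjusted over the lists alone. lg1, which is needed to form the ligule, was higher by 5.20 ± 0.74 in leaf 6 (6.93 without leaf 4 control library 5).

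Leaves 5 and 6 differed as well. wip1, a wound-induced protease inhibitor gene, was higher in leaf 6 controls than in leaf 5 controls by 3.32 ± 0.43, MPI by 3.17 ± 0.36 and RIP by 3.34 ± 0.22, while Igl was lower by -3.29 ± 0.28 and bss1 by -3.35 ± 0.22. CCD8, an enzyme of strigolactone synthesis, was lower in leaf 6 than in leaf 4 by -6.89 ± 0.60 (-7.53 without leaf 6 control library 1). The controls differed for 14270 genes between leaves 5 and 4 (7559 higher and 6711 lower in leaf 5), 18024 between leaves 6 and 4 (9115 and 8909) and 11498 between leaves 6 and 5 (5685 and 5813). Leaf number went with leaf age and, for leaf 4, with the extra handling, and these could not be separated by the design.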

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

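Chosen only after their results were seen were the tests on raised control levels and on a ceiling in leaf 4, both tests on the leaf 4 controls, the splits for the 3 treatments of leaf 4, the protein phosphatase list, the screen of pairs of libraries, the values without single libraries, and the fits without leaf 6 control libraries 5 and 6, without leaf 5 ZmPep3 libraries 1 and 6 and without leaf 4 HAC 30 min libraries 5 and 6.

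The response to each treatment differed between leaves for the numbers of genes below, by tests of the difference itself. The effect of 30 min of HAC differed for 808 genes between leaves 5 and 4, 1341 between leaves 6 and 4 and 92 between leaves 6 and 5. The effect of 2 h differed for 686, 2896 and 445 genes, and the effect of ZmPep3 for 1911, 4759 and 529. Between leaves 6 and 5, the counts were 51 at 30 min and 275 at 2 h without leaf 6 control libraries 5 and 6.

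Fold changes under HAC were smaller in leaf 4 than in leaf 5. Over the 1167 genes that 30 min of HAC raised at least 2-fold in leaf 6, the median log2 fold change was 0.48 in leaf 4 and 1.37 in leaf 5, and over 1327 such genes at 2 h it was 0.31 and 1.12. If raised levels in the leaf 4 controls were the whole cause, genes not higher there than in leaf 5 controls would show no gap. Over 209 such genes at 30 min the median gap was 0.61 (95% bootstrap interval 0.52 to 0.69). Over 458 at 2 h it was 0.79 (0.71 to 0.84). Bootstrap values in this part are over genes that share the same libraries, so they do not measure the spread between replicates. A ceiling on the levels of the 1327 genes as a set in leaf 4 at 2 h is argued against by ZmPep3. It raised them there by a further median of 0.83 (0.76 to 0.89) over HAC. The agents differ in dose and route, so a limit on the response to HAC itself stays open. No such test was made at 30 min. Leaf 4 HAC 30 min libraries 5 and 6 are argued against as the whole cause by the gap over the 1167 genes. It was 0.82 (0.75 to 0.88) without these libraries and 0.94 with them. The within-group SD of leaf 4 and leaf 5 libraries, 0.454 and 0.422 with a ratio of 1.08, has no bearing on a median fold change, and leaf age and the sheath removal of leaf 4 stay open and untested here, since the design changes both together.

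Part of the volatile and jasmonate synthesis transcripts were higher in leaf 4 controls: 13 of 28 members of these lists were lower in both leaves 5 and 6, with a median log2 difference from leaf 5 of 1.64, while over all 28 the median was 0.47 (SD over members 2.20) from leaf 5 and 1.12 (3.02) from leaf 6. A few outlying libraries are argued against for these members, since each of 6 leaf 4 control libraries, held out in turn while members were chosen from the other 5, had a median above the highest of the 12 others (6 of 6, 6.29 to 6.98 against 5.11 to 5.26). These 12, the controls of leaves 5 and 6, were not held out and also served to choose the members. That choice favours low values in them. Handling may have raised such genes, since only leaf 4 had its sheath removed, at least 2 h before treatment. The 1327 genes that 2 h of HAC raised at least 2-fold in leaf 6 stood 0.49 (0.41 to 0.57) higher in leaf 4 than in leaf 5 controls, but this cannot be told apart from leaf age, because all leaf 4 libraries shared this handling.

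Protein phosphatase 2C genes are a family that includes repressors of abscisic acid signalling. Adjusted over the list alone, 8 of 24 had a lower log2 fold change under ZmPep3 in leaf 6 than in leaf 5. Over all genes 3 did. All 8 were above 0 in leaf 5 and all but PP2C24 below 0 in leaf 6, as PP2C3 with 0.68 and -1.04. The differences of the 8, leaf 6 minus leaf 5, ran from -0.71 to -4.82. Their median was -1.70 (bootstrap SD of the median 0.38), and the median of all 24 was -0.38. The list was set after the data were seen, and its camera adjusted p of 2.63e-05 became adjusted p = 0.109 with an estimated correlation. Leaf 6 control libraries 5 and 6 are argued against as the whole cause for these 8. Without them the median was -2.09 (bootstrap SD 0.51), with 7 of the 8 past the threshold over all genes. Without leaf 5 ZmPep3 libraries 1 and 6 it was -1.39 (0.42), with 3 past. This argues against these libraries as the whole cause for the 8, while a part played by them stays open. The 8 were chosen as lower in these same data, which favours a median below 0 in both fits. Leaf age stays open and was not tested.

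In 27 of 240 groups of 6 libraries, 1 library lay far from the others. Its gap to its neighbour, as a share of the range, was past the 95% critical value of Dixon's test. For normal, independent values chance gives about 1 in 20 groups. Gene levels were tested as CPM and the groups shared libraries, so that rate is only a rough guide. For total counts this share was 0.667 in leaf 4 controls, 0.868 in leaf 6 controls, where library 5 had the lowest total, 0.778 in leaf 4 and 0.801 in leaf 6 at 30 min of HAC. For the number of genes detected it was 0.651 in leaf 6 at 30 min, and 0.686 and 0.644 in leaves 4 and 5 at 2 h of HAC. bHLH116 had 0.802 in leaf 6 controls and 0.70 in leaf 6 at 30 min, and WRKY97 0.627 in leaf 4 controls and 0.645 in leaf 4 at 2 h. CYP92C5 had 0.688 in leaf 6 at 30 min, 0.677 in leaf 5 at 2 h and 0.705 in leaf 5 under ZmPep3. lox5 had 0.697 in leaf 4 controls and 0.825 in leaf 6 at 2 h, and MPI 0.629 in leaf 4 controls. PDC (542376) had 0.781 in leaf 5 controls, 0.649 in leaf 6 controls and 0.779 in leaf 6 at 30 min. aox3 had 0.883 in leaf 6 controls, 0.649 in leaf 5 at 2 h, and 0.670, 0.681 and 0.760 in leaves 4, 5 and 6 under ZmPep3. LPE1 had 0.696 in leaf 4 at 30 min and 0.637 in leaf 6 under ZmPep3. The test looks for a single library and misses a pair. Of all 180 pairs of libraries within a group, leaf 4 HAC 30 min libraries 5 and 6 and leaf 5 ZmPep3 libraries 1 and 6 most often held the 2 highest or 2 lowest levels, in 24.4% and 24.1% of genes, against 13.3% for libraries in no order. In leaf 4 at 30 min, libraries 5 and 6 had lox5 at 75.9 and 181 CPM against 290.2 to 542, MPI at 223 and 377 against 736 to 952, and CYP92C5 at 121 and 206 against 267 to 334. In leaf 5 under ZmPep3, libraries 1 and 6 stood apart together, with dxs2 at 301 and 287 CPM against 89.4 to 124, bHLH116 at 107 and 136 against 20.3 to 28.7, and MPI at 115 and 103 against 248 to 307. Without them the ZmPep3 difference of bHLH116 between leaves 5 and 4 was 1.44 ± 0.55, no longer past the threshold, against 2.63 ± 0.61. No cause was tested for these libraries.

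For each of the 27 comparisons, the libraries were also split at random, with 100 splits including the real one and only the groups of the comparison fitted. The share of splits with as many genes was under 0.05 for each of the 18 comparisons in this paragraph, without adjustment for their number. Chance can be excluded at that share, except for leaf 4 at 2 h of HAC, where it stays open. Only the real split gave as many genes, 1 of 100, except where stated. At 30 min of HAC the real split called 865, 2876 and 2056 genes in leaves 4, 5 and 6, and the highest of the others 4, 24 and 48. At 2 h it called 3958 and 5491 in leaves 5 and 6, against 2 and 3. In leaf 4 at 2 h it called 87, and 3 of 100 splits called as many, the highest of the others 293. A random split thus called more genes than the treatment there, and the cause was not tested. For ZmPep3 the real split called 9530, 10318 and 10128 genes, against 112, 7 and 113. Between 2 h and 30 min of HAC it called 1091, 3750 and 5345 genes in leaves 4, 5 and 6, against 0, 24 and 5, and between ZmPep3 and HAC 7313, 5788 and 6319, against 0, 204 and 1. Between controls it called 13587 for leaves 5 and 4, 16580 for leaves 6 and 4 and 9633 for leaves 6 and 5, against 0, 0 and 504.

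For the 9 differences of a response between leaves, treatment labels were exchanged within each leaf. This removes the response itself along with its difference, so these splits cannot show whether chance is excluded for the difference, which rests on the model's test. Between leaves 5 and 4, 2 of 100 splits called as many genes for each treatment, with 675 genes against 1021 at 30 min, 631 against 1359 at 2 h and 1423 against 3283 under ZmPep3. For leaves 6 and 4 the real split called 889, 2596 and 4238 against 725, 124 and 2181. For leaves 6 and 5 it called 245 at 2 h and 335 under ZmPep3, against 1 and 3. At 30 min it called 18, and 2 of 100 splits called as many, the highest of the others 1202. The cause of that high count was not tested.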

How the results depend on the processing

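The fits without leaf 6 control libraries 5 and 6, without leaf 5 ZmPep3 libraries 1 and 6 and without leaf 4 HAC 30 min libraries 5 and 6 were chosen after the data were seen, and the other alternatives before. Of 1270 results for named genes, 933 were past the threshold, and 8457 alternative values were computed. The direction and the side of the threshold were kept in 1254 of 1270 results under DESeq2 size factors, 1248 under the DESeq2 Wald test, 1250 with a block for the replicate number, 1238 without a filter, 1157 when only the groups of the contrast were fitted, 1256 of 1263 under the stricter filter, 444 of 488 without leaf 6 control libraries 5 and 6, 171 of 192 without leaf 5 ZmPep3 libraries 1 and 6, and 133 of 164 without leaf 4 HAC 30 min libraries 5 and 6.

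Counts of genes moved by more than 1.5 times in these cases. With only the groups of the contrast, which means fewer samples to estimate the spread, leaf 4 after 2 h of HAC had 87 genes in place of 431. In the same setting the difference between leaves 6 and 4 at 30 min of HAC had 889 in place of 1341, and the differences between leaves 6 and 5 had 18 in place of 92 at 30 min, 245 in place of 445 at 2 h and 335 in place of 529 under ZmPep3. The DESeq2 Wald test gave 659 genes for leaf 4 after 2 h of HAC, and 205 and 686 for the differences between leaves 6 and 5 at 30 min and 2 h; the cause was not tested. Without leaf 6 control libraries 5 and 6 these differences had 51 and 275 genes, with fewer samples. List calls fell from 222 to 72 with an estimated correlation, which allows for genes that vary together.

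With the controls split 3 and 3, the correlation of HAC and ZmPep3 responses was 0.299, 0.456 and 0.469 in leaves 4, 5 and 6. The agents then shared no control library, and each fold change rested on 3 controls. The effects of these changes on r were not separated. Over genes with a mean of at least 5 CPM, the correlations between leaves 4 and 5, 4 and 6, and 5 and 6 were 0.567, 0.499 and 0.837 for 30 min of HAC, 0.507, 0.353 and 0.803 for 2 h, and 0.821, 0.714 and 0.897 for ZmPep3, with genes of low counts left out.

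The sign reversed in 40 values of named genes, none past the threshold, and the cause was not tested. Without leaf 6 control libraries 5 and 6, these were pep1 at -0.033 and opr8 at -0.007 in leaf 6 at 30 min of HAC, RIP at -0.001 and igl1 at -0.041 in the 30 min difference between leaves 6 and 4, ts1 at -0.008 in the 2 h difference, bx1 at -0.073 and -0.022 in the ZmPep3 differences of leaf 6 from leaves 4 and 5, and lox10 at -0.122 and tps10 at 0.197 in the 30 min difference between leaves 6 and 5. Without leaf 5 ZmPep3 libraries 1 and 6, igl1 stood at 0.018 in leaf 5 under ZmPep3, CYP92C5 at -0.025 and pep1 at -0.224 in the ZmPep3 difference between leaves 5 and 4, rbcS (542212) at 0.064 in that between leaves 6 and 5, and CYP92C5 at -0.040, MPI at 0.170, tps10 at 0.243, TPS2 (732758) at 0.113 and opr7 at 0.030 for ZmPep3 against HAC in leaf 5. Without leaf 4 HAC 30 min libraries 5 and 6, rbcS (542212) stood at -0.034 in leaf 4 at 30 min, opr7 at -0.120 in the 30 min difference between leaves 5 and 4, CYP92C6 at 0.210 and RIP at -0.162 in that between leaves 6 and 4, and lox9 at -0.116, aos1 at -0.358, MPI at -0.276, tps10 at -0.414 and TPS3 (732759) at -0.172 between 2 h and 30 min of HAC in leaf 4. Without a filter, pep1 stood at 0.019 in leaf 5 at 2 h of HAC, bx1 at 0.012 and ME1 at 0.020 in the ZmPep3 difference between leaves 5 and 4, igl1 at 0.066 in that between leaves 6 and 4, and igl1 at -0.008 for ZmPep3 against HAC in leaf 4. With only the groups of the contrast, pep1 stood at 0.012 in leaf 5 and opr8 at 0.00 in leaf 6 at 2 h of HAC, and igl1 at 0.067 in the ZmPep3 difference between leaves 6 and 4. With the replicate block, bx1 stood at 0.008 in leaf 6 under ZmPep3 and igl1 at 0.038 in the ZmPep3 difference between leaves 6 and 4. tps10 stood at -0.015 in the 2 h difference between leaves 6 and 5 under the DESeq2 Wald test, and opr8 at 0.001 for ZmPep3 against HAC in leaf 4 under that test and under DESeq2 size factors.

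In the simulated data at the depth of these libraries, 80% of 2-fold changes were recovered for leaf 5 at 30 min of HAC, so smaller changes were missed more often.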

Other observations

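Lists outside the defence pathways gave these values under ZmPep3. The lists in this part were set after the data were seen. Among 36 cytosolic ribosomal protein genes, 22 rose and 0 fell in leaf 4 under ZmPep3, against 7 and 2 in leaf 5 and 0 and 3 in leaf 6. The leaf 4 list stood above other genes by camera (adjusted p = 5.34e-05), but not with an estimated correlation (adjusted p = 0.347). The response differed between leaves 6 and 4 for 19 of these genes, each lower in leaf 6 (camera adjusted p = 1.95e-12, and adjusted p = 0.413 with an estimated correlation). Auxin response factors moved mainly downward, with 12, 11 and 10 of 20 lower and 1, 4 and 3 higher in leaves 4, 5 and 6. The list was called in leaf 4 by camera at adjusted p = 0.024, with adjusted p = 0.217 with an estimated correlation.

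Genes of cell walls and of light capture differed between control leaves. Of 33 expansin and cellulose synthase genes, 23 were higher and 5 lower in leaf 5 than in leaf 4, and 23 higher and 7 lower in leaf 6 than in leaf 4. Camera gave adjusted p of 1.47e-05 and 0.0122, and with an estimated correlation adjusted p of 0.348 and 0.841. Under ZmPep3, 14 of these 33 genes fell and 3 rose in leaf 4, and the response differed between leaves 6 and 4 for 12 genes in the direction of leaf 6 and 3 in the other. Of 15 nuclear light-harvesting and photosystem genes, 14 were higher and 1 lower in each of leaves 5 and 6 than in leaf 4 (camera adjusted p = 2.77e-07 and 0.000169, and with an estimated correlation adjusted p of 0.348 and 0.713).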
